A study of Mus musculus with 2 samples.

How the data were processed

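Colonic eosinophils of naive C57BL6 mice were profiled in 2 samples, which form 1 group. Per the labels' protocols, colons were digested with enzymes, eosinophils were sorted by flow cytometry, RNA was extracted with Trizol and CEL-Seq libraries were made, 3 technical replicates per sample with different primer pools. The sort gate, the number of cells and the number of mice are not given in the sources used here.

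Per the submitters' processing notes, the tools were STAR 2.4.2a and DESeq, with no version of the latter, and the genome build was mm10. The read counter, its treatment of reads with several alignments, the annotation release and the transcript lengths are not given in the sources used here. The deposited table has 31295 rows, 1 per placed RefSeq transcript, with 2 value columns: a read total and an RPKM. Per the file headers, the RPKM values are reads per kilobase of transcript per 1000000 reads, computed by the authors. The read totals deposited by the authors are not raw counts: 100% of them times 6 are whole within 0.0001, and 48.8% are whole themselves, as a mean over 6 libraries would be. RPKM was 0 exactly where the read total was 0. Each column is 1 value for the whole group, so it is printed as the authors' mean with no SD or n. There were 0 columns of other samples.

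Because RPKM divides by length and CEL-Seq reads 1 region near the 3′ end, short transcripts are raised and long ones lowered. Reads per 1000000 reads on genes (RPM), without length, were therefore used as an alternative, chosen after the table was seen. Gene symbols were brought to current names through RefSeq accessions for 30726 rows, symbols for 405 and synonyms for 85; 79 kept their own symbol, and 2306 symbols changed. One row per gene, the transcript with the most reads, was kept, which left 23456 genes. Of 30348 transcripts also in GENCODE M21, 99.4% were on the same chromosome and 40.6% had the same start, so coordinates are used as given, in mm10.

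Read totals times 6 gave the reads over all libraries, with exact Poisson intervals at 95%. A count of 0 was given an upper limit of 3 reads. Library depths were found from 1277 transcripts with 1 read in all: the read total divided by RPKM and length is then the depth of the library that held the read, and 718 of them lay within 1% of a depth. Depths were placed at the fullest windows of 0.002% of the implied depth, a narrower width than that 1%. The libraries were not assigned to the samples.

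Gene lists were fixed before the data were examined: 24 functional lists and 17 lists of other cell types, with 463 genes, of which 36 are in more than 1 list. Igj, Trac and Ly6g were not matched, and Jchain, the current name of Igj, is also in its list. Named genes followed a fixed rule. It takes the 20 genes with the highest RPKM, the 4 highest members of each list (2 are allowed for the interferon, NADPH oxidase and housekeeping lists), and members listed at 0 as a count with up to 3 names. Its last part, genes that differ between the 2 samples, was not possible. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen. For each list the median RPKM was set against 10000 random lists of the same size, drawn from genes at an RPKM of 1 or more and the members; random lists were not matched on expression, which is the quantity measured.

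Shared sequence was measured as the percent of 35-base words in the last 500 bases of the longest matching GENCODE M21 transcript that also occur in a transcript of another gene. It was searched for 558 of 565 genes. Copies outside annotated transcripts were not searched, since no genome sequence was used here, and strand use in counting is not given, so antisense partners cannot be told apart.

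Of the 6 planned results, 3 were computed: genes detected, the level of the granule list, and the eosinophil lists against other cell types. The other 3 compare the 2 samples (their agreement, the genes that differ and the shifts of the lists) and were not computed, since values per sample were not analysed here. Alternatives were other detection minimums, RPKM rescaled to a sum of 1000000, leaving out ribosomal protein rows, RPM, the transcript with the highest RPKM, other list summaries and backgrounds, and members with under 50% shared words.

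Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Methods were tested on simulated data: the largest error of 6 simulated depths was 7.5e-07%, 4.5% of random lists fell outside the central 95%, and 100% of lists planted among the highest of 7282 genes lay above it.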

Results

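Eosinophils, granulocytes that reside in the gut wall in health, were sorted by flow cytometry from enzymatically digested colons of naive C57BL6 mice. The data hold 1 group of 2 samples of these colonic eosinophils. Messenger RNA was measured with CEL-Seq, which reads tags near the 3′ end of transcripts, and each sample was made into 3 technical libraries with different primer pools. The table gives 1 mean read total and 1 mean RPKM (reads per kilobase of transcript per 1000000 reads) per transcript, averaged by the authors over the 6 libraries. No value per sample was analysed here, so no SD, n or test between samples is given. The intervals below are exact 95% Poisson intervals of the reads over the 6 libraries, scaled to RPKM by 1 factor per gene. They cover counting error only. Unequal library depths were not taken into account, so on RPKM the intervals are approximate. The labels name no molecular identifiers, so reads copied from 1 molecule by amplification are counted as separate reads.

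The 23456 genes held a mean of 1282064.5 reads per library, or 7692387 reads over the 6 libraries. Transcripts with a single read in all 6 libraries gave the depth of each library, as the value that turned that read into its RPKM. These depths were 1892486, 2070937, 2100580, 2396564, 4343107 and 4752357 reads, with 35 to 96 transcripts in a window of 0.002% at each depth. The next fullest window of that width, over 0.1% from each depth, held 2. The depths summed to 17556031 reads, of which the reads on genes were 43.8%. For a count of 0 over the 6 libraries, an upper limit of 3 reads, one-sided unlike the intervals, was used, equal to 0.390 reads per 1000000 reads on genes (RPM).

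**Figure D1:**
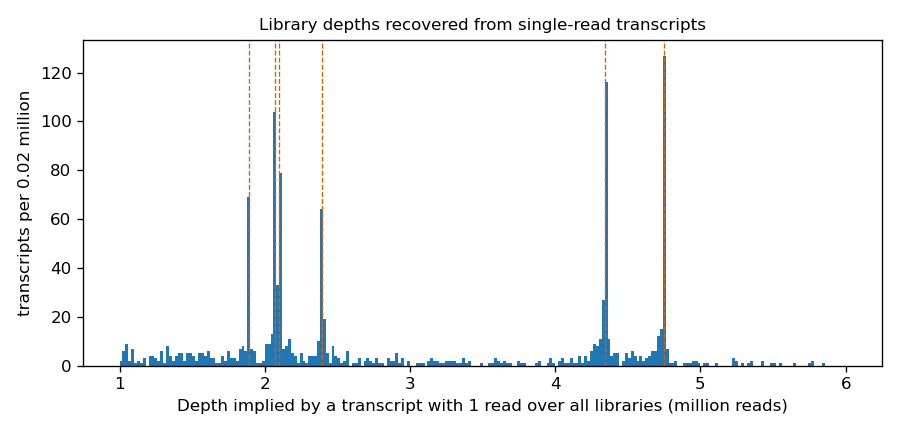
Library depths recovered from single-read transcripts. The horizontal axis is the depth, in units of 1000000 reads, implied by each transcript with 1 read over all 6 libraries, the vertical axis the number of transcripts per bin, and dashed lines mark the 6 depths, from 1892486 to 4752357 reads.

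The first question was which transcripts were most abundant in the sorted samples from naive mice, after digestion and sorting. Srgn, the core protein of the proteoglycan that packs granule contents, was the most abundant transcript, with an RPKM of 25417 (25338 to 25496). Retnlg, a secreted resistin-like protein, followed at 11986 (11917 to 12054), ahead of B2m, the light chain of class I major histocompatibility molecules, at 5983 (5942 to 6024). Pla2g7, the secreted enzyme that inactivates platelet-activating factor, reached 5084 (5059 to 5110), and the neutrophil-attracting chemokine Cxcl2 reached 5035 (5002 to 5069). This order is that of RPKM. By reads without length, Pla2g7 ranked 2, Retnlg 3, Cxcl2 7 and B2m 9. In the mm10 coordinates of the table, Srgn (NM_011157) lies on chromosome 10 from 62494428 to 62507755 and Retnlg (NM_181596) on chromosome 16 from 48872608 to 48874498.

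The next genes by RPKM were S100a11 at 4745, the chemokine Ccl6 at 4133, the translation initiation factor Eif1 at 3752 and the NF-kB inhibitor Nfkbia at 3373. Rpl4 of the large ribosomal subunit stood at 2602, S100a6 at 2574, Spi1, which encodes the myeloid transcription factor PU.1, at 2196 and the cytoskeletal actin Actb at 1788.5. Jun followed at 1679, Sh3bgrl3 at 1639, the mRNA decay factor Zfp36 at 1471 and the peptidoglycan-binding protein Pglyrp1 at 1436. The list of 20 closed with the cell cycle inhibitor Cdkn1a at 1394, the integrin chain Itgb2 at 1291 and the peroxide-reducing enzyme Gpx1 at 1261. Of S100a11, 48.5% of the searched sequence words are also in another gene, so its value is uncertain.

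An RPKM of 1 or more was reached by 7282 genes, 31.05% of those measured. Of all genes, 16204 were above 0, 2059 reached 10, 301 reached 100 and 29 reached 1000. The 20 highest genes held 37.4% of the summed RPKM, and the 20 with the most reads held 23.5% of the reads, with 5.12% in Srgn alone. The number of detected genes moved to 16204 for any RPKM above 0 and 3323 at an RPKM of 5. It was 11938 at an RPM of 1 and 11134 at 1 on RPKM rescaled to the same sum of 1000000, where the gene RPKM summed to 237589. RPKM divides by transcript length although a 3′ tag does not grow with length, and 15 of the 20 genes were also among the 20 with the most reads.

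The level of the eosinophil granule protein genes was the next question. Prg2, which encodes the major basic protein, had an RPKM of 74.3 (70.0 to 78.7) from 1132 reads over the 6 libraries. The ribonuclease Ear6 stood at 8.35 and the second major basic protein gene Prg3 at 1.17. Epx, the eosinophil peroxidase gene, had 0.265 (0.132 to 0.474) from 11 reads and was named after its value was seen, and Ear1 had 0.803. Ear2 and Rnase2a were listed at 0. In total 3 of 7 granule genes reached an RPKM of 1, and the median was 0.803.

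That median lay below every one of 10000 random lists of 7 genes drawn from the granule genes and genes at an RPKM of 1 or more, and at the 53.0th percentile of lists drawn from all genes above 0. On RPKM rescaled to a sum of 1000000, which lets lower genes into the first background, it lay at the 11.7th percentile. For Ear1 and Ear2, 73.4% and 51.9% of the searched sequence words are also in another gene, for Rnase2a 3.43% and for Epx and Prg3 0%; the glycolytic enzyme gene Eno1, used by nearly all cells, is also listed at 0, so a 0 here says only how the gene is listed.

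Genes of the eosinophil surface identity list, which holds some genes that other myeloid cells also express, were abundant, with 12 of 13 at an RPKM of 1 or more and a median of 68.4, above all 10000 random lists. Alox5ap, a nuclear membrane protein that is also in the lipid mediator list and presents arachidonic acid to 5-lipoxygenase, had an RPKM of 236, the eotaxin receptor Ccr3 155 (152 to 159), the F4/80 antigen Adgre1 109 and the tetraspanin Cd63 93.2. Siglecf, the sialic acid-binding lectin commonly used to sort these cells, stood at 77.9 (75.1 to 80.8), the interleukin-33 receptor Il1rl1 at 75.6 and the interleukin-5 receptor chain Il5ra at 18.6. Hrh4, at 0.0452 from 1 read, was the member below 1. Siglecf, Il5ra and Hrh4 fall outside the rule for named genes and were chosen after their values were seen. Of Cd63, 63.7% of the searched sequence words are also in another gene.

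All 11 lineage transcription factor genes reached an RPKM of 1, with a median of 7.26 at the 84.0th percentile. Spi1 led at 2196, followed by Cebpb at 304.4, Trib1, a pseudokinase of granulocyte differentiation, at 107 and Id2 at 32.9. Gata1, the factor required for the eosinophil lineage, stood at 30.0 and was named after its value was seen. Of the genes used as markers of intestinal eosinophils, 8 of 10 reached an RPKM of 1, with a median of 11.7 at the 95.7th percentile, and the 98.1th by RPM. Vegfa had 247.5, Thbs1 131.5, the integrin chain Itgax 83.6 and the aryl hydrocarbon receptor Ahr 52.2. The checkpoint ligand Cd274 had 14.4 and Cd80 2.66. The members below an RPKM of 1 were Ahrr at 0.4997 and Clec4a4 at 0.143, the latter from 3 reads over the 6 libraries. Cd274, Cd80, Ahrr and Clec4a4 were named after their values were seen.

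Inhibitory and activating paired receptor genes had a median of 21.1 at the 99.99th percentile, with 14 of 16 at an RPKM of 1 or more. Lilrb4a had 1236, the signalling adaptors Tyrobp and Fcer1g 1131 and 450.3, and the low-affinity IgG receptor Fcgr3 148. All of the searched sequence of Lilrb4a is shared with another gene, so its value is uncertain. Cd200r3 and Pira2 were listed at 0.

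Secreted signals were uneven. Among cytokine genes 13 of 21 reached an RPKM of 1, with a median of 3.80 at the 38.1th percentile by RPKM and the 0.125th by RPM. Il1b had 263, Il1a 200.1, the receptor antagonist Il1rn 115 and oncostatin M, Osm, 46.1. The type 2 cytokine genes Il4 and Il13 had 3.28 and 1.11, values looked up after the list was seen. The 4 cytokine genes listed at 0 include Csf2, Il12b and Il17a. Among chemokine genes 12 of 18 reached an RPKM of 1, with a median of 8.79 at the 95.9th percentile by RPKM and the 13.2th by RPM, led by Cxcl2 at 5035, Ccl6 at 4133, Ccl9 at 759.5 and Ccl3 at 555. The eotaxin gene Ccl24 was listed at 0.

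Receptors for these signals were led by Csf2ra, the ligand-binding chain for granulocyte-macrophage colony-stimulating factor, at 525. The decoy receptor Il1r2 followed at 107.5, Il1rl1 at 75.6 and the shared beta chain Csf2rb at 68.4. The cytokine receptor list had a median of 9.50 at the 97.505th percentile, with 17 of 21 genes at an RPKM of 1 or more. In the chemoattractant receptor list 8 of 14 genes reached an RPKM of 1, with a median of 3.27 at the 25.3th percentile by RPKM and the 2.51th by RPM. Cxcr4, the receptor for the retention chemokine Cxcl12, had 438, Ccr3 155, the complement receptor C3ar1 29.8 and Ccr1 29.3.

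Lipid mediator genes had a median of 29.9 at the 99.95th percentile, with 10 of 12 at an RPKM of 1 or more. Pla2g7 had 5084, the 5-lipoxygenase Alox5 309, Alox5ap 236 and the 12/15-lipoxygenase Alox15 229.9. All 14 genes of the NADPH oxidase and antioxidant list reached an RPKM of 1, with a median of 77.7 above all random lists. Gpx1 had 1261, and the oxidase subunits Cyba, Ncf1 and Cybb had 990, 727 and 402.

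The S100 and antimicrobial list had a median of 10.7 at the 97.55th percentile by RPKM but the 6.30th by RPM, with 11 of 16 genes at an RPKM of 1 or more. Retnlg, S100a11, S100a6 and S100a10 led it at 11986, 4745, 2574 and 762. Pattern recognition and inflammasome genes had a median of 3.34 at the 24.3th percentile by RPKM and the 0.800th by RPM, with 12 of 20 at an RPKM of 1 or more. Ly96, the partner of the endotoxin receptor, had 21.1, Casp1 17.8, Casp4 17.1 and Tlr13 12.8, and Tlr9 was listed at 0. Complement genes had a median of 3.36 at the 29.2th percentile, with 9 of 12 at an RPKM of 1 or more. Properdin, Cfp, had 49.2, C1qb 37.9, C3ar1 29.8 and Cr1l 21.8. Interferon response genes had a median of 1.35, with 9 of 15 at an RPKM of 1 or more, led by Ifitm3 at 161 and Isg15 at 71.9.

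Antigen presentation genes had a median of 10.5 at the 97.9th percentile, with 12 of 16 at an RPKM of 1 or more. B2m had 5983, the class II invariant chain Cd74 507, H2-K1 331 and H2-D1 183. Adhesion and integrin genes had a median of 45.0 above all random lists, with 14 of 15 at an RPKM of 1 or more. Itgb2 had 1291, Cd44 605, the tetraspanin Cd9 596 and Itgb7, a chain of the gut-homing integrin, 176. Matrix remodelling genes had a median of 3.53 at the 34.0th percentile, with 11 of 15 at an RPKM of 1 or more. The transglutaminase Tgm2 had 564, Thbs1 131.5, Adam8 56.0 and the adhesion protein Tgfbi 47.2.

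Survival and apoptosis genes had a median of 8.90 at the 94.8th percentile by RPKM and the 98.5th by RPM, with 14 of 16 at an RPKM of 1 or more. The kinase Pim1 had 623, the anti-apoptotic Mcl1 199.8, Birc3 184 and the death receptor Fas 120.5. Glycolysis genes had a median of 8.69 at the 93.0th percentile by RPKM and the 99.4th by RPM, with 10 of 14 at an RPKM of 1 or more. Aldoa had 324, Pkm 157, Gpi1 92.5 and Ldha 67.2, and Eno1 was listed at 0. Without the 2 members with 50% or more shared words, the list median was 15.3.

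The dissociation list, of immediate early genes and some heat shock genes, was the highest. All 17 reached an RPKM of 1, with a median of 186 above all random lists. Whether dissociation induced them in these samples was not tested, as the data hold no undigested sample. Jun had 1679, Junb 1240, Fosb 1210.3 and the phosphatase Dusp1 682. The NF-kB and activation feedback list had a median of 40.8 above all random lists, with 12 of 13 genes at an RPKM of 1 or more. Nfkbia had 3373, Zfp36 1471, Nfkbiz 121 and Nfkb2 60.5. Both lists stand beside the high Cxcl2 and Il1b, and the labels place an enzymatic digestion before the sort.

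Cell cycle genes had a median of 1.08, with 8 of 15 at an RPKM of 1 or more. Top2a had 6.84, Mki67 2.70, Birc5 1.67 and Ccnb2 1.66, and Bub1 was listed at 0. In the housekeeping list 8 of 12 genes reached an RPKM of 1, with a median of 3.22 at the 25.4th percentile by RPKM and the 5.71th by RPM. Actb had 1788.5, whereas Gapdh had 0.781 and Ppia 0.0476, both named after their values were seen. Of the searched sequence of Gapdh and Ppia, 94.0% and 56.7% is shared with another gene, and without the 3 members with 50% or more shared words the list median was 13.9. Pgk1 had 0.373 with 10.7% shared words and the glycolytic gene Pgam1 0.0816 with 0%, both also named after their values were seen.

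**Figure D2:**
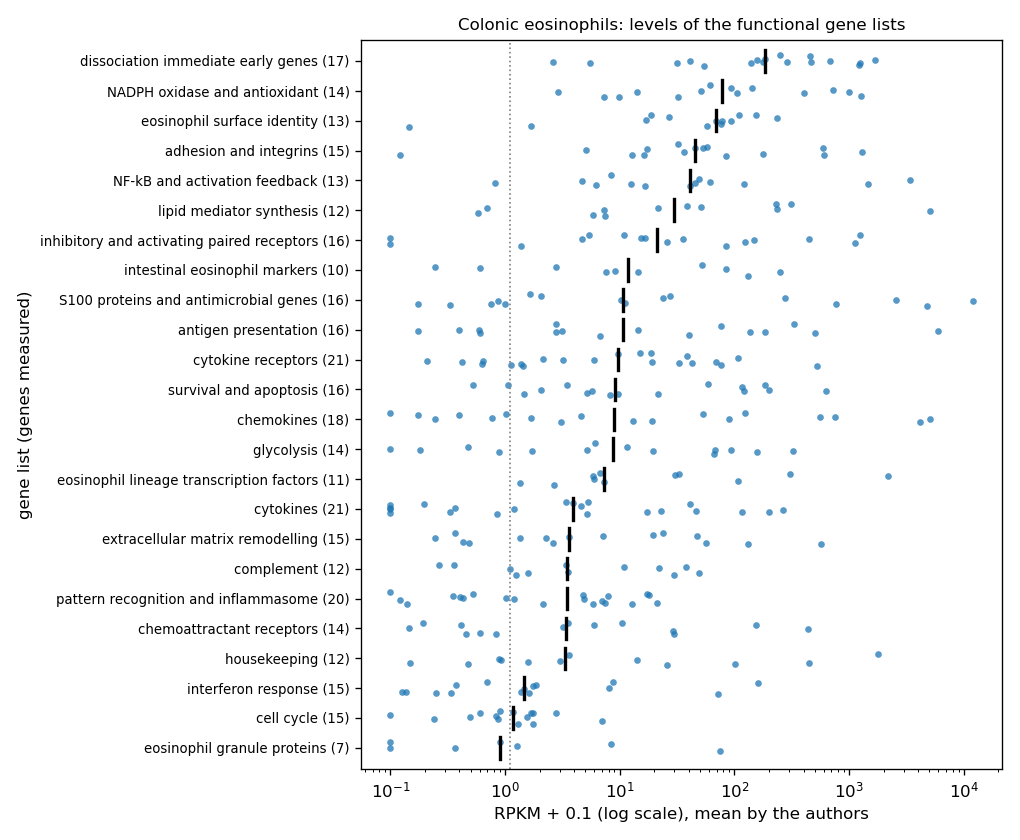
Levels of the 24 functional gene lists in colonic eosinophils. Each point is 1 gene at its RPKM plus 0.1 on a log axis, black bars are list medians, the dotted line marks an RPKM of 1 and the number of genes is in parentheses; immediate early genes are highest at 186 and granule proteins lowest at 0.803.

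The last question was how far the eosinophil lists stand from markers of other cell types that a colon sort could hold. The median of the surface identity list, 68.4, was above the median of all 17 other cell type lists, and the other eosinophil lists were not. The median of the intestinal marker list, 11.7, was above 14 of them, that of the lineage factors, 7.26, above 13 and that of the granule genes, 0.803, above 11. The erythrocyte and platelet list came closest at 44.2, with Hbb-bs at 559.9, Hba-a1 at 379, Hba-a2 at 377 and Hbb-bt at 69.3. At least 65.9% of the searched words of each of these globin genes are in another gene, so their values are uncertain. The treatment of reads with several alignments is not given, so the values could be too low or too high. Hba-a1 and Hba-a2 list the same mean of 762 reads. Without the 4 globin genes the list median was 6.02, below the goblet, fibroblast and epithelial medians of 19.1, 16.1 and 10.9. Leaving them out does not show that globin RNA was absent. On mean log2(RPKM + 1) the erythrocyte and platelet list stood at or above the identity list, leaving 16 of 17 lists below it.

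Epithelial and goblet cell markers were present throughout. All 13 epithelial genes reached an RPKM of 1, with a median of 10.9 at the 96.7th percentile, and Epcam had 89.3 (86.3 to 92.3), Krt19 66.7, Car4 38.6 and Lgals4 30.1. All 8 goblet genes did so too, with a median of 19.1 at the 98.5th percentile by RPKM but the 73.0th by RPM, and the secreted lectin Zg16 had 46.7, the mucin Muc2 30.8, Tff3 27.6 and Spink4 20.8. Fibroblast genes had a median of 16.1, at the 97.45th percentile by RPKM and the 98.5th by RPM, with 7 of 8 at an RPKM of 1 or more, and Col3a1 had 66.7, Col1a2 35.2, Dcn 23.8 and Col6a1 23.2. Smooth muscle genes had a median of 4.98, with 5 of 6 at an RPKM of 1 or more, and Acta2 had 34.8, Tagln 6.85, Myh11 6.69 and Des 3.28.

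Macrophage and monocyte genes had a median of 2.34, with 7 of 12 at an RPKM of 1 or more. Apoe had 54.3, Csf1r 41.0, C1qb 37.9 and C1qc 10.7, the last 2 also in the complement list, and Mertk was listed at 0. Neutrophil genes had a median of 0.386, with 3 of 11 at an RPKM of 1 or more. These were Retnlg at 11986, S100a9 at 23.9 and S100a8 at 10.2, with Ltf next at 0.908; all 4 are also in the S100 and antimicrobial list. Elane and Mpo were listed at 0.

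The remaining 10 lists had medians under an RPKM of 1. Plasma cell genes had a median of 0.568, with 3 of 7 at an RPKM of 1 or more, and the immunoglobulin joining chain Jchain stood apart at 44.1 from Mzb1 at 1.83, Sdc1 at 1.33 and Derl3 at 0.568. Of Mzb1, 99.8% of the searched words are in another gene. Basophil genes had a median of 0.0988, with 2 of 6 at an RPKM of 1 or more, and the histidine decarboxylase Hdc had 14.5, Gata2, also a lineage factor, 5.75, Mcpt8 0.166 and Prss34 0.0316. Endothelial genes had a median of 0.424, with 2 of 8 at an RPKM of 1 or more, and Plvap had 12.4, Egfl7 1.19, Tek 0.718 and Cdh5 0.535. Genes of group 2 innate lymphoid cells had a median of 0.453, with 3 of 8 at an RPKM of 1 or more. Of these, Klrg1 had 8.04, and Areg at 3.80, Il13 at 1.11 and Il7r at 0.524 are also in the cytokine or cytokine receptor lists.

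Enteroendocrine genes had a median of 0.548, with 2 of 6 at an RPKM of 1 or more, led by the peptide gene Pyy at 4.94, Chga at 1.66, Chgb at 0.587 and Cck at 0.51. Enteric glia and neuron genes had a median of 0.733, with 3 of 6 at an RPKM of 1 or more, led by Sox10 at 2.14, Gfap at 1.49 and Uchl1 at 1.15. T and NK cell genes had a median of 0.434, with 4 of 11 at an RPKM of 1 or more, led by Cd4 at 1.56, Cd3e at 1.44, Gzmb at 1.11 and Cd3g at 1.06. B cell genes had a median of 0.187, with 1 of 8 at an RPKM of 1 or more, led by Cd79b at 1.15 and Blk at 0.481.

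Dendritic cell genes had a median of 0.0873, with 1 of 8 at an RPKM of 1 or more, and Batf3 had 4.10, Ccr7 0.256, Clec9a 0.199 and Xcr1 0.0936. Mast cell genes had a median of 0.0800, with 2 of 9 at an RPKM of 1 or more, and Mcpt1 had 2.47, Mcpt2 1.15, Cma1 0.346 and Cpa3 0.319. Mast cells had 4 genes listed at 0, among them Mcpt4, Ms4a2 and Tpsab1, and basophils 2, Cd200r3 and Fcer1a. Tph1, Tnfrsf17, Rora, Pax5 and Cd209a were each the 1 gene listed at 0 in the enteroendocrine, plasma cell, innate lymphoid, B cell and dendritic cell lists.

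Of the 41 lists, 12 had a median above the central 95% of random lists of the same size and 14 below it. Random lists came from genes at an RPKM of 1 or more, which lowers any list with members under 1. Against all genes above 0, 3 of the 14 stayed below the central 95%, those of dendritic cells, mast cells and basophils, and the lists above it rose from 12 to 22, of which 18 are functional.

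**Figure D3:**
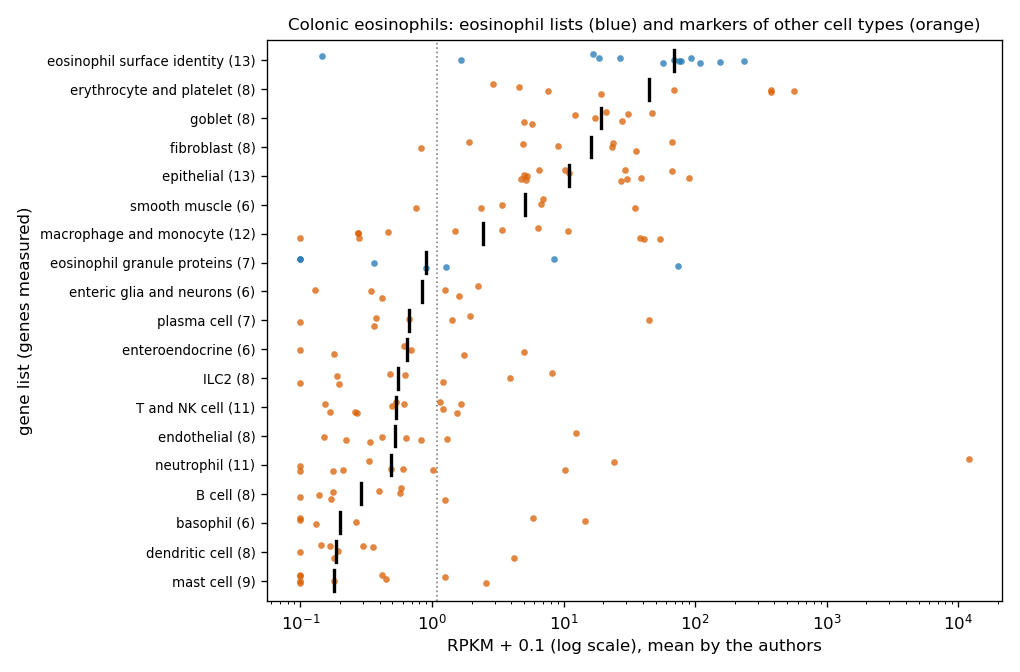
Eosinophil lists in blue and lists of other cell types in orange. Each point is 1 gene at its RPKM plus 0.1 on a log axis. Black bars are list medians and the dotted line marks an RPKM of 1. Surface identity stands highest at 68.4, and the erythrocyte and platelet list follows at 44.2. Without its 4 globin genes, whose values could be too low or too high, the erythrocyte and platelet median was 6.02.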

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

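RPM (reads per 1000000 reads on genes), the transcript with the highest RPKM and the shared-word filter were chosen only after the data were seen. Of 15 alternatives run, 8 left the result within 1.5 times (counts) or inside the counting interval (the granule median in RPKM). The other background, which cannot move a median, is not counted among them. That interval, 0.323 to 1.66, is the counting error of Ear1 alone, the gene at the median, from 7 reads. It does not measure the spread of the list. The 7282 detected genes moved to 16204 for RPKM above 0, 3323 at 5 or more, 11134 on RPKM rescaled to a sum of 1000000 and 11938 on RPM. The granule median of 0.803 was 3.38 on rescaled RPKM. Rescaling multiplies every gene by 1 factor, so neither rescaled value bears on stability. The median was 1.43 in RPM, another unit not comparable with the RPKM interval, and 1.17 without members of 50% or more shared words. Its percentile was 0 as reported, 11.7 on rescaled RPKM and 53.0 against all genes above 0; the first background holds no other gene under 1. The identity list was above 16 of 17 other lists by mean log2 and above 17 in the other alternatives. By RPKM 12 lists lay above the central 95% of random lists, by RPM 14, with 10 in both: the S100 and goblet lists left, and the intestinal marker, survival, glycolysis and fibroblast lists entered. Not run, for lack of values per sample or library here: without replicate 1, without replicate 2, the median of technical columns, leaving out each technical column, other pseudocounts, median-ratio scaling and all alternatives of the 3 results that compare the samples. No paired analysis was possible because there is 1 group and 1 pooled column. Depth limits genes near 0: a count of 0, taken as at most 3 reads, allows an RPM of 0.390.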

Other observations

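The tests on sequence shared by the ribosomal genes, Epx and Retnlg were set before their results were seen; the tests on Ear1 and Ear2, ribosomal genes with few shared words, the S100 genes, the read rank, the epithelial markers and the library depths were chosen only afterwards, as were the copy of Eno1 and the transcripts placed at several loci. Of other cell types in the sort, only neutrophils and epithelial cells were examined as technical sources. No biological explanation was tested, because the data hold 1 group.

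Genes ranked 21 to 60 by RPKM, read after the values were seen, hold further genes that no list named. Cyp4f18, which inactivates leukotriene B4, had an RPKM of 1116 (1105 to 1128). The iron store Fth1 had 1044, the flow-responsive transcription factor Klf2 704 and the metallothionein Mt1 613. Leukocyte membrane and cytoskeletal genes were also there, with Cd37 at 582, Coro1a at 564, the leukocyte common antigen Ptprc at 549 and Basp1 at 533. The NF-kB regulator Nfkbid had 524, beside Nfkbia at 3373.

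The 1st pattern is genes near 0 that other cells transcribe at high levels. Among 77 cytosolic ribosomal protein genes, the 46 with 50% or more of their words in another gene had a median RPKM of 0.918 and the other 31 a median of 6.40, a ratio of 0.143, so reads shared with pseudogenes or paralogs may lower part of them; across genes, which are not independent replicates, Spearman's rho was −0.23 (two-sided permutation p = 0.0424). The Eno1 copy Gm5506 on chromosome 18 from 48045335 to 48048383 held a mean of 107.7 reads and Eno1 0. Of coding accessions placed at several loci, 95.2% had 0 reads at each, against 34.95% of those placed once. These accessions were not matched on gene family or expression. The contrast therefore cannot separate reads lost to copies from genes not transcribed in these cells. Shared words of Ear1 and Ear2, at least 51.9%, leave reads shared with pseudogenes or paralogs open as an explanation for them. Epx shares 0% of its words and Rnase2a 3.43%, as Pgam1 shares 0% and Pgk1 10.7%. For Epx this argues against reads shared with another annotated transcript only. Copies outside annotated transcripts were not searched, and Pgam1 stood at an RPKM of 0.0816, so the low level of all 4 stays open. Of the 31 ribosomal genes with fewer shared words, 11 had an RPKM under 1. For these, shared reads cannot be told apart from other causes without a search of the genome.

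The 2nd pattern is Retnlg, a gene of the neutrophil list, at rank 2 by RPKM. S100a9 reached 0.199% of the Retnlg level and S100a8 0.0854%, with an upper limit of 0.231% that covers counting error only. This argues against neutrophils or their RNA as the source of Retnlg, as far as the S100a8 and S100a9 values hold. Genes with 0% shared words can be listed near 0 for reasons left open above, as Pgam1 is at 0.0816. The neutrophil list gene Ly6g was not matched. Only 1.72% of the words of Retnlg are in another gene, which argues against reads shared with another annotated transcript. It ranked 3 by reads without length, which argues against length normalization. Transcription of Retnlg in the sorted eosinophils was not itself tested and remains a hypothesis, from the same data in which the pattern was found.

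The 3rd pattern is epithelial and stromal markers in sorted eosinophils. All 21 epithelial and goblet markers, 100%, had an RPKM of 1 or more against 31.05% of all genes. Of the markers, 0 are in another list, and Epcam led at 89.3. This count restates the pattern, so it adds no separate support for a source. Epithelial cells or their RNA in the sort remain a candidate source, though the labels name a flow sort. The reads of 20 of the markers implied a median depth of 3096519 reads (quartiles 2879841 and 3279271), 28.7% from the nearest library depth. This argues against 1 library alone holding the markers. All genes with 20 or more reads per library implied 2984874, and 1 of the 2 samples holding most of the markers stays open, as libraries were not assigned to samples. Fibroblast and smooth muscle markers and the erythrocyte and platelet list were not tested for a source. The erythrocyte and platelet list had the highest median RPKM of other cell types, 44.2, and 6.02 without its 4 globin genes. Shared sequence could make the globin values too low or too high, so the lower median does not show that globin RNA was absent.

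Haemoglobin rows that overlap at 1 locus hold the same reads: Hbb-b1 and Hbb-bs both list a mean of 1172 reads, and Hba-a1 and Hba-a2 both list 762. The list values of Hba-a1 and Hba-a2 come from these overlapping rows, so they do not stand for separate reads. Both genes also have rows at another locus on chromosome 11, from 32296489 and 32296492, each with a mean of 426 reads.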
